A study of Caenorhabditis elegans with 4 samples.

How the data were processed

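The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of Caenorhabditis elegans embryos of strain OP51. Its worms carry a lin-13 transgene tagged with TY1, EGFP and FLAG in an unc-119(ed3) background and were grown at 20 °C. Per the labels' protocols, embryos were cross-linked with formaldehyde, chromatin was sonicated and precipitated with a goat antibody against GFP, and the recovered DNA was size selected and sequenced on an Illumina platform. The labels name 4 libraries: 2 of ChIP DNA and 2 of input DNA, the sonicated chromatin before precipitation, numbered as replicates 1 and 2 of each kind.

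The only values analysed were 1 peak list in GFF3 format, in which the authors combined both replicates. Each of its 5502 rows gives a chromosome, a start, an end and a q-value. The source column of the deposited list names PeakSeq, a caller that compares ChIP reads with scaled input reads in candidate regions, and the coordinates are those of WormBase WS180, per the file headers. The PeakSeq version, aligner, fragment length, input scaling and read filters are not given in the sources used here. The deposited q-value appears both as the score and as an attribute, and both were equal in all 5502 rows. All q-values lay below 0.01. Starts and ends are base positions counted from 1, so the width of a peak is its end minus its start plus 1. No read count, peak height or fold enrichment is in the list, so the depth per sample is unknown from it. Because the replicates were combined before deposition, no value per library was at hand, and neither ChIP with input nor replicate 1 with replicate 2 could be compared across libraries. Nothing in the list measures the spread between replicates, and every p-value below describes the arrangement of peaks in this single list.

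No genome or annotation of WS180 was used, and the gene table at hand belongs to another assembly, so peaks were not assigned to genes. The planned share of peaks at transcript starts and the planned enrichment of 24 fixed gene lists were therefore not computed. By the rule fixed before the data were examined for this case, the peaks named are the 10 with the smallest q-value and the strongest peak of each chromosome. The closing section also names peaks with the highest ratio of implied ChIP to input reads, chosen after their values were seen. Chromosome length was taken as the end of the last peak on that chromosome, since lengths of WS180 were not used here.

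Peak density on X against the autosomes, and on each chromosome against the others, was tested with 100000 random placements in proportion to chromosome length. Density in chromosome centres, defined as the middle 50% of each chromosome, was tested against the arms with 100000 random placements within chromosomes. Clustering was tested as the share of peaks whose midpoint lay within 2 kb of another midpoint, against 10000 random placements within chromosomes. The relation between −log10 q-value and width was measured as Spearman's rho across peaks with 100000 permutations. Peak widths and the share of top-ranked peaks per chromosome were compared with 10000 permutations of the chromosome labels. All tests were two-sided, and values over the 6 chromosomes were adjusted by the Benjamini-Hochberg method. Since peaks cluster, density ratios also carry a 95% interval from 10000 bootstrap draws of whole 1 Mb windows. Peaks were also ranked by q-value, and the 2751 peaks with the smallest q-values are called top-ranked. The comparisons of chromosome II, of width between chromosomes, of centre shares by rank, of dense windows and of peaks narrower than 100 bp were chosen after seeing the data.

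Alternatives were the top-ranked peaks alone, peaks closer than 500 bp merged, covered base pairs in place of peaks, a centre of the middle 33.3%, placement within 1 Mb windows, correlation within each chromosome and without the widest 1% of peaks. Chosen after seeing the data were the exchange of whole 1 Mb windows, the removal of peaks narrower than 100 bp and a raise of the implied input reads by 1.23 times on II or on the autosomes. Read numbers implied by the q-values were reconstructed by a method given with its test in the closing section. The placement tests and the reconstruction were tested on simulated data with known answers. Reads were recovered for 100% of 2777 simulated peaks. Their q-values were built with the formula that the reconstruction inverts, so this checks the code and not how the peak caller worked. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used.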

Results

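LIN-13 is a nuclear zinc-finger protein of the class B synthetic multivulva genes, which act with the Rb homologue LIN-35 to restrain vulval cell fates and other developmental programmes. The series asked where a GFP-tagged LIN-13 binds the genome in embryos. ChIP DNA from 2 replicates was compared by the authors with 2 libraries of input DNA, and 1 combined list of binding regions resulted. The list held 5502 peaks on the 6 nuclear chromosomes, or 55.0 peaks per Mb. They covered 1958 kb, which is 1.96% of the 100.05 Mb spanned. The numbers of reads per library are not in the list, and values for single replicates were not analysed here, so no value below carries a replicate error.

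Most LIN-13 peaks were short. The median width was 303 bp, with quartiles of 200 and 433 bp, and the range ran from 1 to 3368 bp. Only 148 peaks were 1 kb or wider, and 490 peaks (8.91%) were narrower than 100 bp. No peaks overlapped, and the smallest gap between neighbours was 200 bp. The median gap was 8147 bp. The q-values, as the authors' peak caller gave them, ranged from 6.19e-125 to 0.00996 with a median of 2.92e-04. A q-value under 1e-10 was reached by 766 peaks (13.9%), one under 1e-20 by 238 peaks (4.33%) and one under 1e-50 by 21 peaks.

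The peak with the smallest q-value, by which peaks are called strongest here, lay on chromosome II, from 14249144 to 14251947 (WormBase WS180), with a width of 2804 bp and a q-value of 6.19e-125. A q-value depends on the number of reads as well as on enrichment. The second was on chromosome IV, from 14032433 to 14035008, with a width of 2576 bp and a q-value of 1.79e-103. The third was the strongest on chromosome I, from 9988512 to 9989442, at a q-value of 4.94e-95. The strongest peak of the X chromosome ranked next and spanned 11605071 to 11606553 with a q-value of 9.29e-79. Chromosome IV held 3 more of the 10 strongest peaks. They lay at 7485865 to 7486981 with a q-value of 5.46e-77, at 654728 to 655115 with 2.99e-70 and at 8333188 to 8334821 with 5.58e-70. The strongest peak of chromosome III, at 3867377 to 3867750, had a q-value of 2.77e-72. Chromosome II held the remaining pair, at 11633873 to 11635362 with a q-value of 1.10e-69 and at 11759154 to 11759648 with 4.11e-69. None of the 10 strongest peaks lay on chromosome V, whose strongest peak, at 10341768 to 10342705, had a q-value of 4.65e-52 and ranked 18 in the list. The 10 strongest peaks had a median width of 1300 bp, but 3 of them were under 500 bp wide, namely those at 3867377 on III, at 654728 on IV and at 11759154 on II. Genes at these positions were not identified, because no annotation of this build was used.

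**Figure D1:**
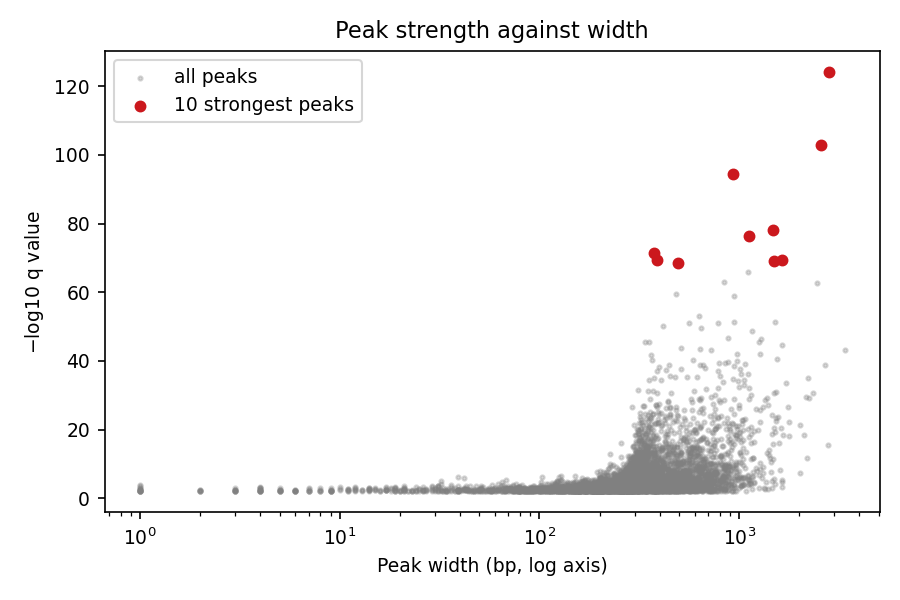
Each grey point is 1 of the 5502 peaks, placed by its width in bp on a log axis and by the −log10 of its deposited q-value; red points are the 10 strongest peaks. Peaks with the smallest q-values were mostly wide, and nearly all peaks narrower than 100 bp sat at the bottom of the q-value scale.

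Wider peaks had smaller q-values. Across the 5502 peaks, Spearman's rho between −log10 q-value and width was 0.55 (permutation p = 1e-05, the smallest that 100000 permutations can give). Peaks are not independent replicates, and the correlation describes this list. Within single chromosomes rho lay between 0.47 on X and 0.64 on II. The 2751 top-ranked peaks had a median width of 368 bp, against 216 bp for the 2751 lower-ranked peaks. Of the 490 peaks narrower than 100 bp, 468 (95.5%) were lower-ranked.

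The X chromosome carried fewer LIN-13 peaks per Mb than the autosomes, and its peaks were wider. It held 701 peaks, or 39.7 per Mb, against 58.3 per Mb on the 5 autosomes together. The density ratio of X to autosomes was 0.68 (95% interval 0.60 to 0.773 over 1 Mb windows; permutation p = 1e-05, the smallest possible). The median width was 374 bp on X, against 303 bp in the whole list. The geometric mean width was 1.44 times that of all other peaks (permutation adjusted p = 1.5e-04). Very narrow peaks weigh heavily on a geometric mean. Peaks narrower than 100 bp made up 2.71% of those on X, against 8.91% of the list, and widths were not compared without them. Measured as covered base pairs, the ratio was 0.849 (permutation p = 3e-04). With the input reads implied by the q-values raised 1.23 times on the 5 autosomes and not on X, the density ratio was 1.14 (permutation p = 0.0025). The same raise would keep only 58.8% of the peaks on X, so raising the autosomes alone lifts the ratio whatever caused the deficit. No input factor was resolved on X. Top-ranked peaks made up 54.9% of those on X, against 50% of the whole list (permutation adjusted p = 0.0093). The shares on III (55.8%, permutation adjusted p = 0.008) and on I (54.7%, permutation adjusted p = 0.0069) were similar in size.

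Chromosome II had the highest density of the 6 chromosomes. Its 1314 peaks, 23.9% of the list on 15.3% of the spanned length, came to 86.03 per Mb (95% interval 77.6 to 96.8). The other 4 autosomes together had 52.0 per Mb, which gives a ratio of 1.66 (95% interval 1.43 to 1.93; permutation p = 1e-05). Chromosome I was the next densest, at 62.7 peaks per Mb, and V followed at 56.1, IV at 46.2 and III at 41.4. Against all other chromosomes, I and II lay above random placement and III, IV and X below it (adjusted p = 3.6e-05 or lower in each permutation test). These placements treat peaks as independent, though peaks cluster, and whole windows were exchanged only for X and II. Over 1 Mb windows the 95% intervals were 56.4 to 68.9 per Mb on I, 32.1 to 54.6 on III and 38.3 to 54.9 on IV. Each comes close to the 55.0 per Mb of the whole list, so the evidence for these 3 is weaker than their p-values. For chromosome V, with a ratio to the rest of 1.03, the permutation test found no difference from random placement (adjusted p = 0.454). Peaks on II were narrow, with a median of 263 bp and a geometric mean width 0.784 times that of the rest (permutation adjusted p = 1.5e-04). Peaks on V were narrow as well, at a median of 277 bp and a geometric mean 0.866 times the rest (permutation adjusted p = 1.5e-04). Peaks narrower than 100 bp, which weigh heavily on these means, made up 12.5% of those on II and 11.7% on V. Chromosome V also had the lowest share of top-ranked peaks, 42.1% (permutation adjusted p = 6e-04), while for II, at 48.5%, no difference from the list was found (permutation adjusted p = 0.266). The density ratio of II was 1.62 among top-ranked peaks alone. It was 0.993 after the input reads implied by the q-values on II were raised 1.23 times, the ratio between the input factors fitted for I and II. The same raise would remove a like share of peaks from any chromosome, so it does not show a cause.

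**Figure D2:**
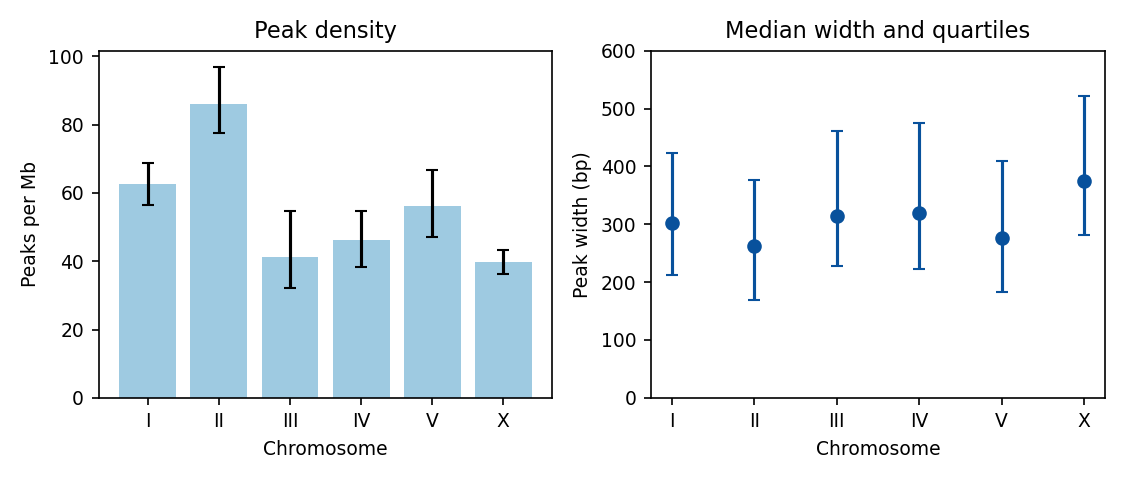
Left, peaks per Mb on each chromosome, with 95% intervals from bootstrap draws of 1 Mb windows as error bars; right, the median peak width in bp with its quartiles. Chromosome II reached 86.03 peaks per Mb and X 39.7, while the median width was 263 bp on II and 374 bp on X.

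LIN-13 peaks were more frequent on the chromosome arms than in the centres. In C. elegans the centres are rich in conserved and broadly expressed genes, and the arms are rich in repeats and carry much of the heterochromatin. The middle 50% of the chromosomes held 2319 peaks (42.1%, Clopper-Pearson 95% interval 40.8 to 43.5, counting error only), against 3183 on the arms. The density was 46.4 peaks per Mb in the centres and 63.6 on the arms, a ratio of 0.729 (95% interval 0.610 to 0.812; permutation p = 1e-05). The ratio was below 1 on each of the 6 chromosomes, from 0.597 on III (permutation adjusted p = 1.5e-05) to 0.85 on X (permutation adjusted p = 0.034). These placements treat peaks as independent, though peaks cluster, and whole windows were exchanged only for all chromosomes together. The evidence for single chromosomes is therefore weaker than their p-values. On III, 115 of the 218 peaks in the left outer part lay in the window from 1000001 to 2000000. The left and right outer parts, whose difference was not tested, held 329 and 158 peaks on IV, 218 and 139 on III and 288 and 382 on V. They held 256 and 280 on I, 379 and 375 on II and 185 and 194 on X.

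The arm preference was larger among lower-ranked peaks. Of the top-ranked peaks 45.7% lay in the centres, against 38.6% of the lower-ranked, a difference of 7.16 percentage points (permutation p = 1e-05). The top-ranked share was the larger on all 6 chromosomes, most on V, with 50.3% against 37.3%, and least on X, with 47.01% against 44.6%. Among top-ranked peaks alone the centre-to-arm ratio was 0.843. Peaks narrower than 100 bp lay in the centres in only 23.9% of cases, and without them the difference by rank was 3.27 percentage points (permutation p = 0.021).

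**Figure D3:**
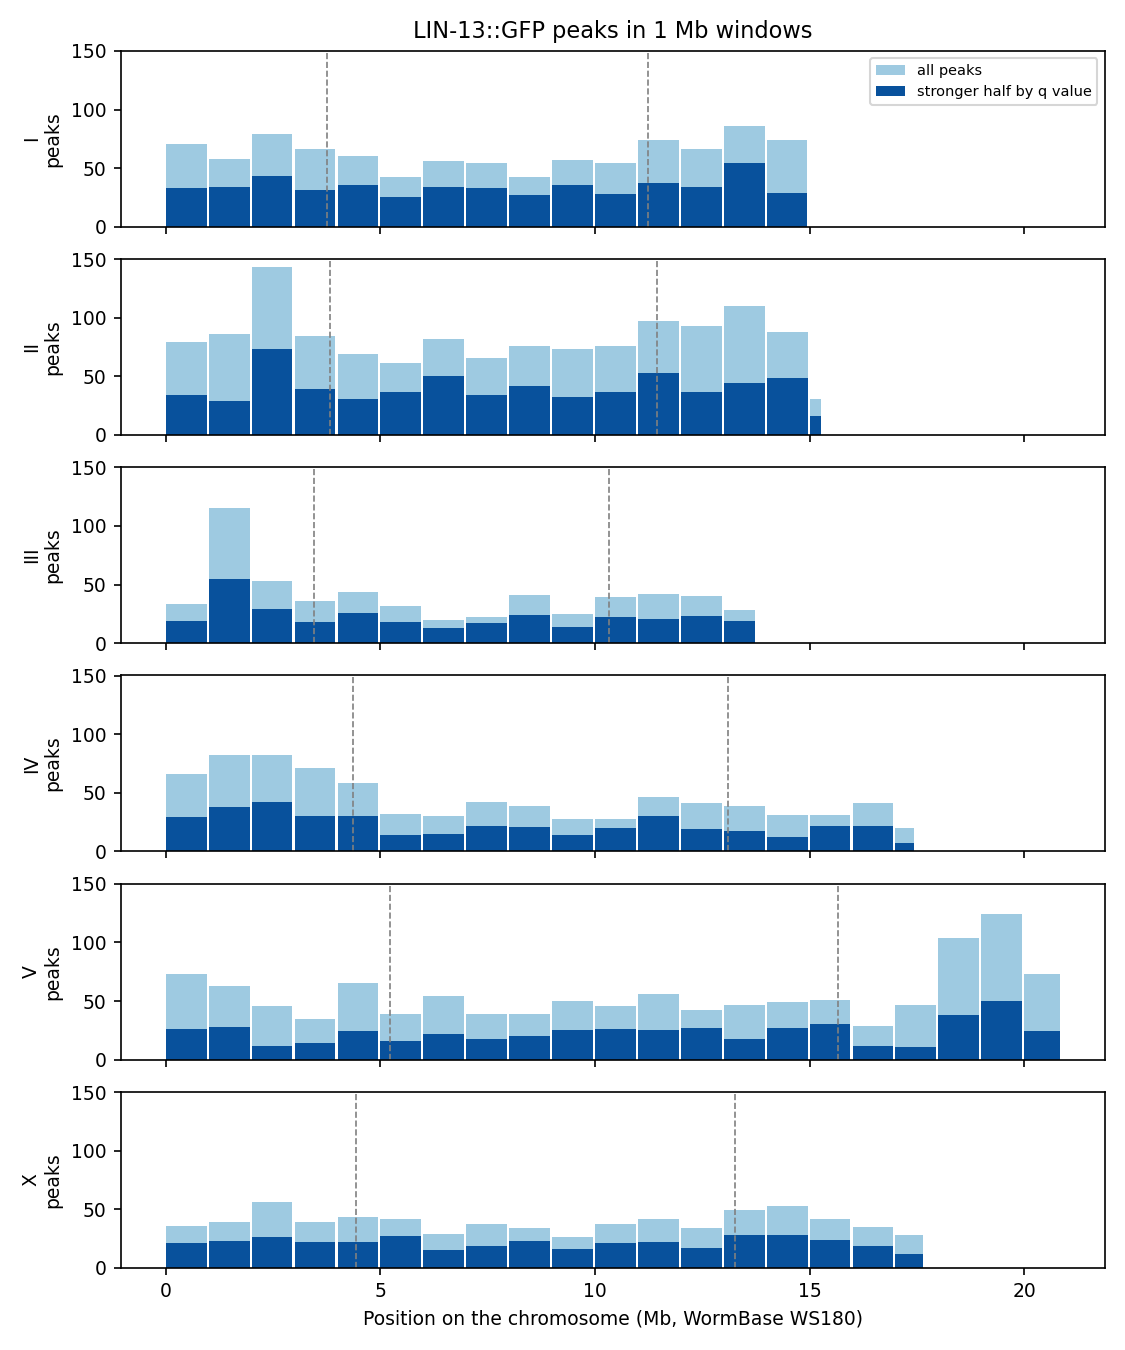
Number of LIN-13::GFP peaks in 1 Mb windows along the 6 chromosomes (position in Mb, WormBase WS180); light bars are all peaks, dark bars the 2751 top-ranked peaks, and dashed lines bound the middle 50% of each chromosome. The densest windows lie on the arms of II, V and III, with 143, 124 and 115 peaks.

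Peaks lay closer together than chance. A neighbour within 2 kb was found for 32.8% of peaks, against 20.9% ± 0.713 (SD over random placements) for randomly placed peaks (permutation p = 1e-04, the smallest that 10000 placements can give). With placement kept within 1 Mb windows the random value was 22.2%. The excess fell from 11.8 to 3.05 percentage points when peaks closer than 500 bp were merged. Merged regions cannot lie within 500 bp of each other, whereas the random placements could. Part of the fall is therefore built in, and it does not show at what range the excess lay. Merging left 5139 regions, of which 22.6% had a neighbour within 2 kb against 19.6% at random (permutation p = 2e-04). The densest 1 Mb window was chromosome II from 2000001 to 3000000, with 143 peaks, and in 2000 random placements the fullest window of the genome never exceeded 127. The window from 19000001 to 20000000 on V held 124 peaks (permutation p = 0.0015) and that from 1000001 to 2000000 on III held 115 (permutation p = 0.015). At a scale of 100 kb the densest stretch was III from 1500001 to 1600000, with 31 peaks, where random placement gave at most 25. Its peaks had a median width of 208 bp and 15 of the 31 were top-ranked.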

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

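The comparisons of X with the autosomes, II with the other autosomes and centres with arms, the centre share by rank, the clustering and the relation of q-value and width kept their direction and their side of 0.05 under the alternatives to the choice of peaks, centre or placement given here. The changes to the implied read numbers, described with chromosome II among the other observations, are not among these. Raising the input on II took its density ratio to 0.993 (permutation p = 0.859), so its excess was lost. Raising it on the autosomes took the ratio of X from 0.68 to 1.14 (permutation p = 0.0025), so its direction reversed. Such a raise removes a like share of peaks from any chromosome, so neither outcome shows a cause. The changes to the read numbers, the exchange of whole 1 Mb windows, the removal of peaks narrower than 100 bp and the alternatives for chromosome II and for the centre share by rank were chosen after seeing the data. Keeping only the top-ranked peaks left 2751 peaks by construction. The density ratio of X to the autosomes ranged from 0.68 to 0.849, that of II from 1.59 to 1.66 (1.49 with peaks joined at 2000 bp) and that of centres to arms from 0.705 to 0.843. The excess of peaks with a neighbour within 2 kb was 11.8 percentage points as deposited and 7.005 with the top-ranked peaks. It was 10.5 with placement within 1 Mb windows and 3.05 after merging at 500 bp. Merging removes the closest neighbours from the list but not from the random placements, so this last fall is partly built in. The share of peaks at transcript starts and the enrichment of gene lists were not run, for want of an annotation of this build. No paired analysis was possible because both replicates were combined in 1 list before deposition, and leaving out a replicate was not possible for the same reason. Depth limits the list through its unknown read numbers: a region absent from it was not called at a q-value of 0.01, which does not show that LIN-13 was absent there.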

Other observations

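All tests in this part were chosen after the data were seen, and only for both tests of chromosome II was the prediction written before the outcome. The q-values carry more than a rank, because each of them appears to encode the reads behind its peak. In deposited order, each q-value times its rank equals 26301 times the tail of a fair binomial distribution of whole read numbers. This held for 5502 of the 5502 peaks within 1e-11 on the natural log scale, and for 0 peaks if 26301 was raised or lowered by 1. It is consistent with 26301 candidate regions tested, of which the list keeps 20.9%. A single pair of read numbers was implied for 5501 peaks and more than one for the last, which was left out. The larger number is read here as ChIP and the smaller as scaled input, and the input may be off by 1 read if the caller counted the tail differently.

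On this reading LIN-13 enrichment was moderate at most sites and high at a few. The median peak had 72 ChIP reads against 28 input reads, and the median ChIP-to-input ratio was 2.64, with quartiles of 2.17 and 3.38. A ratio of 5 or more was reached by 353 peaks, and 800 peaks (14.5%) had a ratio under 2. The strongest peak by q-value, at 14249144 on II, had 1010 ChIP reads and 203 input reads, a ratio of 4.98. Among peaks with at least 100 reads in total, the highest ratios, a choice made after the values were seen, belonged to the short peaks at 11759154 on II (348 against 27 reads, ratio 12.9) and at 654728 on IV (359 against 29 reads, ratio 12.4). Next came 12343583 to 12343892 on V (173 against 16 reads, ratio 10.8) and 1868606 to 1868978 on V (192 against 18 reads, ratio 10.7). Across peaks the Spearman correlation of width was 0.94 with total reads and -0.31 with the ratio. The q-value limit itself pushes the latter below 0, since a peak with few reads enters the list only with a high ratio. The ratio was lowest on X, with a median of 2.31, and highest on II, with 2.85. At matched total reads, the difference in log2 ratio from all other chromosomes was -0.18 on X (SE 0.0204), -0.10 on III (SE 0.022) and 0.13 on II (SE 0.0142), each with a permutation adjusted p of 0.001. This order rests on the scaled input. Multiplied by the input factors fitted in the next paragraph, the median ratio is 1.23 on II, 1.42 on I, 1.76 on III and on V 2.18 or 1.22 with its 2 nearly equal fits, so that II no longer has the highest ratio. With the next-best factors, which fitted less well, it is 0.858 on II, 0.925 on I and 0.992 on III, so the size of the unscaled ratio is uncertain. X has no resolved factor. The values come from combined libraries and carry no replicate error.

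The implied input reads have an uneven histogram with regularly repeated excess values, as whole numbers have after multiplication by a factor under 1 and rounding up. A fit of such a factor, chromosome by chromosome, improved the likelihood beyond all 200 smooth simulated histograms on 4 chromosomes (I, II, III and V) for input reads and on 0 chromosomes for ChIP reads. The best factors were 0.532 on I, 0.431 on II and 0.72 on III, while V fitted 0.796 and 0.444 almost equally well and IV and X were not resolved. Input reads per kb were counted over the width of each peak plus 200 bp, which lowers the value more for narrow peaks. Dividing the median of these values by the factors gives 106 on I, 110 on II and 96.8 on III. On V it gives 58.3 with the best factor, 0.796, and 104.5 with 0.444, so near-equal input on all 4 chromosomes holds only with the second choice for V. The next-best factors give 163 on I, 157 on II and 172 on III. A candidate explanation is that the input was scaled separately for each chromosome. Of the 40 peaks with the most scaled input reads per kb, 27 lay on III, which holds 10.4% of the peaks. The median peak had 69.7 scaled input reads per kb on III and 70.5 on X, so the chromosome median does not single out III. What sets these peaks apart was not tested, and they are no evidence for separate scaling.

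The excess of peaks on chromosome II was weighed against a splitting of wide domains and a lower input factor. Joining peaks closer than 2000 bp left a density ratio of II to the other autosomes of 1.49, against 1.66 as deposited, so splitting does not account for most of it. Raising the input on II by 1.23 times, to the factor fitted for I, left 788 of its peaks under the largest nominal p in the list and a density ratio of 0.993. That shows that a scaling difference of this size would be enough. It does not show that it was the cause, since the same raise, tried after that result was seen, would keep only 57.0% to 63.2% of the peaks on the other chromosomes, near the 60.0% on II, and since V may have a factor as low as that of II without an excess. A difference in input scaling and a true difference in LIN-13 binding cannot be told apart for chromosome II. The deficit on X is open to the same doubt. Scaled input was 70.5 reads per kb on X and 69.7 on III, the least dense chromosomes, against 46.4 to 56.5 on the others, in the median peak. The way reads per kb were counted lowers narrow peaks more, and peaks on X were wider, so part of this difference comes from width. With the same raise on the 5 autosomes and none on X, tried after these values were seen, the density ratio of X was 1.14, against 0.68 as deposited. A rise had to follow, since the raise removes a like share of peaks from any chromosome and would keep only 58.8% on X. It shows only that a scaling difference of this size would be enough. No factor was resolved on X, so whether its input was scaled differently is unknown.

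The arm preference of lower-ranked peaks was weighed against lower enrichment on the arms. At matched total reads the arms had a higher log2 ratio than the centres, by 0.088 (SD over shuffled peak labels 0.0129, permutation p = 1e-04). This argues against lower enrichment of the listed peaks on the arms. Regions that missed the q-value limit were not compared. Matching used 20 bins of total reads, so lower totals within a bin may raise the ratio on the arms. Peaks on the arms had fewer reads, with a median total of 90 against 117 in the centres, and the median was lower on the arms of all 6 chromosomes. Within chromosomes, the mean log2 total on the arms minus that in the centres was -0.36 (SD over shuffled peak labels 0.0235, permutation p = 1e-04). Since a q-value follows from the total and the ratio, the lower totals restate the weaker q-values and do not explain them. A scaling factor per chromosome is shared by its arms and its centre. It also affects which regions enter the list, so whether it bears on the totals of the arms was not settled. Lower mappability of repeats and narrower binding on the arms were not tested and stay open.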
